A study of Mus musculus with 2 samples.

How the data were processed

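Single cells sorted from the lateral striatum of male mice were measured by droplet RNA sequencing in 2 libraries, 1 from the side of the occluded middle cerebral artery (ipsilateral) and 1 from the opposite side (contralateral). Per the labels, striata of 3 animals were pooled in each library before dissociation, and cells were sorted for the surface antigens A2B5, O4 or both. The deposited values are counts of unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule) per gene and barcode, made with Cell Ranger 3.1.0 on the mouse build mm10, per the submitters' processing notes. The alignment options and the gene annotation are not given in the sources used here. The deposited matrices list only barcodes kept as cells, so the RNA of empty droplets was not measured here.

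Choices made before the data were examined were the filters, the clustering settings, the marker and gene lists, the rule for named genes and most of the alternatives. Cells were kept with at least 500 detected genes, at most 15% mitochondrial UMIs and no doublet call. Scrublet, run in scanpy 1.11.5 on each library with its default expected rate of 0.05, set its score threshold at 0.274 in the contralateral and 0.154 in the ipsilateral library. The expected rate had not been fixed in advance: a first look at the data used 0.02, which called 12 barcodes in each library, and the tool's default was taken as the main setting after that. At the default it called 14 contralateral barcodes (0.73%) and 101 ipsilateral barcodes (4.03%), an uneven removal whose effect is given with the alternatives. The 1899 contralateral and 2404 ipsilateral cells left were scaled to 10000 counts each, log-transformed and clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1, without integration.

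Clusters took the name of the class whose fixed markers they expressed, with "-like" added because names rest on RNA alone. The scoring thresholds were set after the data were seen. A cluster stayed unnamed if its best score was under 0.3, or if under 3 markers reached 0.3 of their highest cluster level. The same held if a second class scored at least 0.3 and reached 0.6 of the best score. It held too if the 10 leading genes included more markers of another class than of its own. Clusters with median UMIs under their libraries' median divided by 3 stayed unnamed if none of those 10 genes was an own marker. Clusters 2, 4, 11 and 12 stayed unnamed on these rules and held 11.3% of contralateral and 9.53% of ipsilateral kept cells. Cluster 11 mixed microglia and fibroblast markers at a median of 1430 UMIs, and cluster 12 mixed markers of precursors and mature oligodendrocytes at a median of 39312.5 UMIs, as doublets would. Cluster 12 held 35 contralateral and 13 ipsilateral cells, whereas Scrublet had called more ipsilateral barcodes.

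UMIs were summed per library and class and expressed as CPM, the usual library-size scaling, of the class total. The log2 ratio, ipsilateral over contralateral, was taken after adding 5 CPM to both values, which draws ratios of low genes toward 0. Each group is 1 library, so no test was made and no p-value is given. Sums carry exact Poisson 95% intervals and shares exact binomial 95% intervals, both for counting error only; intervals of differences of shares were combined from these by Newcombe's method. For a gene list, the median log2 ratio over members with at least 20 summed UMIs is given with its percentile among 10000 random lists of equal size matched on mean expression, as a description of these libraries. Which lists are described was chosen after their medians were seen. Of the lists measured, 9 of 35 lay above and 9 below the central 95% of random lists in OPC-like cells, 4 and 11 of 33 in committed cells, and 14 and 5 of 37 in mature cells. Shares of cells with a UMI were compared after thinning each cell to a fixed number of UMIs.

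The genes named in a main class are the 10 largest and 10 smallest log2 ratios among genes with at least 50 summed UMIs and at least 20 CPM in a library. Mitochondrial, ribosomal protein and predicted or clone-named genes were left out, and secondary classes give 5 genes each way. Up to 4 members of each described list with the largest absolute ratio, and the class markers Pdgfra, Gpr17 and Mbp, were also named; a further marker of the rule is not reported here. Sequence shared between genes was measured as the percentage of a gene's 31-base words found in transcripts of another gene, in GENCODE M21 on the GRCm38 (mm10) build.

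The steps were tested on simulated sums of the OPC-like class over 31053 genes. For true log2 ratios of 1, 2, -1 and -2, in 50 genes each, medians were 0.88, 1.83, -0.85 and -1.47 with the added 5 CPM, and 88%, 90%, 96% and 98% of intervals held the true value. Of 200 unchanged lists, 1.0% lay outside the central 95% of random lists. The simulated sums were independent Poisson counts per gene, without spread between cells or genes that move together. These rates may therefore not hold for the real lists and genes. Alternatives varied the filters, doublet handling, clustering, scaling (including the trimmed mean of M-values of edgeR 4.0.16), the added CPM and the minimum of UMIs; they were run for the 3 oligodendrocyte-lineage classes only. Python 3.11.15 and R 4.3.3 were used.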

Results

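Single-cell RNA sequencing compared oligodendrocyte-lineage cells from the injured and the opposite side of the brain after stroke in young mice. The middle cerebral artery was occluded for 60 minutes on postnatal day 10, and the lateral striatum was taken after 2 weeks of reperfusion. A2B5 marks early glial progenitors and O4 later stages of the lineage, so the sort spans precursors to mature oligodendrocytes. The contralateral library held 2066 barcodes and 36063045 UMIs (median 13238.5 per barcode), the ipsilateral library 2775 barcodes and 54788795 UMIs (median 17607). With 1 library of 3 pooled animals per side, the differences below have no replicate check, and all intervals cover counting error only.

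Mature oligodendrocyte-like cells made up a larger share of the ipsilateral library, while oligodendrocyte precursor (OPC)-like cells held the same share on both sides within counting error. Mature cells were 27.5% of contralateral kept cells (95% interval 25.5 to 29.6) and 39.6% of ipsilateral ones (37.6 to 41.6), a difference of 12.1 points (9.21 to 14.9). Much of this difference lay in mature cluster 18, with 9 contralateral cells (0.47% of kept cells) and 187 ipsilateral ones (7.78%). A cluster drawn so unevenly can reflect its library. Of the other mature clusters, clusters 0, 3 and 15 were higher ipsilaterally and cluster 9 was lower (6.21% and 3.99%). OPC-like cells were 16.6% on both sides, and their difference of -0.04 points had an interval of -2.33 to 2.22. Committed or newly formed oligodendrocyte-like cells were 6.79% and 9.15%, a difference of 2.36 points (0.70 to 4.00), which was 0.46 points with no filter on cells and 5.79 points with each library clustered alone. Neuroblast or neural progenitor-like cells were lower ipsilaterally, at 21.4% against 14.5%, as were endothelial-like cells at 9.53% against 5.20%. Astrocyte-like cells were 6.11% and 4.78%, and mural cells 0.74% and 0.62%.

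Among oligodendrocyte-lineage cells alone, OPC-like cells were 32.6% contralaterally and 25.4% ipsilaterally, and mature cells 54.0% and 60.6%. The sort and the recovery of each cell type set part of these shares. The 6.57-point difference of mature cells within the lineage was -2.04 points when each library was clustered alone and 1.41 points under a stricter filter on cells. The 12.1-point difference over all kept cells was 6.05 points under that filter.

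**Figure D1:**
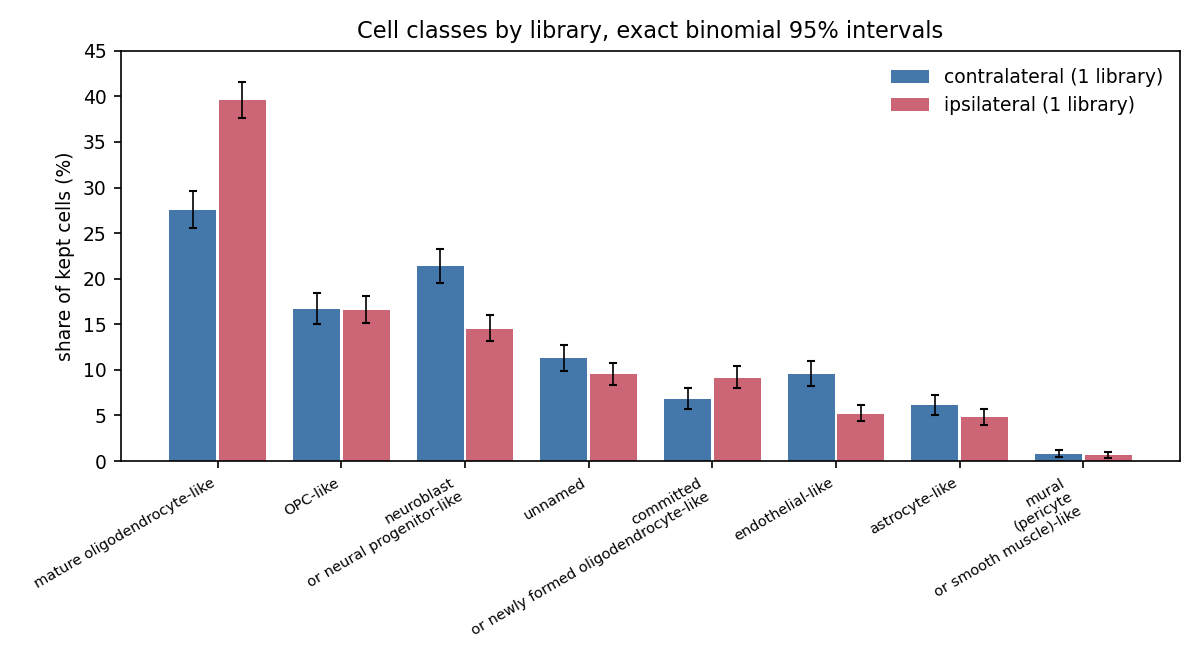
Share of kept cells (%) in each cell class for the contralateral and ipsilateral libraries, 1 library each; bars are shares and whiskers exact binomial 95% intervals. Mature oligodendrocyte-like cells stand at 27.5% and 39.6%, and OPC-like cells at 16.6% in both.

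In OPC-like cells, genes of DNA replication and mitosis, interferon-response genes and reactive glia genes were higher in the ipsilateral library, and targets of BMP, Notch and Wnt signalling were lower. All 18 measured S phase genes had ratios above 0, with a median log2 ratio of 0.70 (percentile 100). Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, was 18.3 CPM contralaterally and 49.7 CPM ipsilaterally, and Mcm2, part of the replicative helicase, 16.5 and 36.6 CPM. All 20 G2/M genes were above 0, with a median of 0.56 (percentile 100); the proliferation marker Mki67 was 43.0 and 86.7 CPM, and Top2a 91.6 and 192 CPM. Contralateral OPC-like cells lay mostly in cluster 10 (73.1%) and ipsilateral ones mostly in cluster 6 (53.6%). With both libraries weighted to the same mix of these clusters the S phase median was 0.36 and the G2/M median -0.25. The clusters themselves differed in cycle genes: in cluster 6 over cluster 10 the G2/M median was 3.40 in the contralateral and 3.20 in the ipsilateral library. In cells with no microglia UMI the G2/M median between libraries was 0.24.

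The share of OPC-like cells with UMIs of at least 2 cycle genes was 62.0% (56.1 to 67.6) contralaterally and 66.9% (61.9 to 71.7) ipsilaterally, each cell thinned to 6301 UMIs, which left out 32 and 24 cells. The difference of 4.96 points had an interval of -2.61 to 12.6, so no difference was detectable at this depth; it was 9.27 points at Leiden resolution 0.5, 2.84 points with no filter on cells, -0.56 points at the same mix of clusters and -1.55 points when clustered without response genes. Without thinning the shares were 77.2% and 83.5%, at median depths of 10125 and 12538 UMIs. Endothelial-like cells thinned to the same depth gave 70.3% and 59.4% and mature cells 34.6% and 36.1%, so this share includes background and is not read as a share of dividing cells.

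Of 19 measured interferon-response genes, 18 were above 0 in OPC-like cells, with a median of 0.76 (percentile 100). Bst2, which tethers budding virus, was 0.59 CPM (2 UMIs) and 14.1 CPM (81 UMIs), and Ifit1 2.65 and 13.4 CPM; the largest single cell held 35.8% of the ipsilateral Bst2 UMIs. These are low counts, and the median was 0.27 with 20 CPM added in place of 5 and 1.39 with 1 CPM. Of 9 reactive glia genes 8 were above 0 (median 0.73, percentile 100), among them the filament gene Vim at 72.2 and 146 CPM and S100a10 at 5.89 and 25.1 CPM; this median was 0.27 with 20 CPM added and 0.14 with no minimum of UMIs. MHC class I genes had a median of 0.14, with Psmb8 at 4.42 and 11.9 CPM; it was 0.086 (percentile 94.9) in cells with no microglia UMI and 0.32 at the same mix of clusters. Immediate early genes, which dissociation can induce, had a median of 0.13, with Junb at 588 and 1003 CPM, and of 0.26 in cells with no microglia UMI. The higher interferon list was not particular to OPC-like cells, with medians of 0.84 in committed, 0.86 in astrocyte-like and 0.39 in endothelial-like cells. It was 0.13 in mature and 0.10 (percentile 83.3) in neuroblast-like cells. A shift of the whole library was not tested for this list.

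Of 14 BMP, Notch and Wnt target genes 12 were below 0 in OPC-like cells, with a median of -0.40 (percentile 0.0). The Notch targets Hes1 and Hes5 were 292 and 172 CPM and 319 and 191 CPM, and Nrarp 154 and 90.4 CPM. The median was -0.15 at the same mix of clusters. Lipid uptake and export genes had a median of -0.25, with Apoe, a lipid carrier, at 2284 and 1218 CPM; the median was -0.16 at the same mix. Markers of other cell types moved too: all 8 astrocyte markers were below 0 (median -0.32), and mature oligodendrocyte markers had a median of 0.28, against 0.70 in endothelial-like and 0.38 in neuroblast-like cells. The astrocyte marker median was -0.036 (percentile 40.4) at the same mix of clusters, and the mature marker median 1.90 with each library clustered alone.

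Of the genes with the largest ratios in OPC-like cells, Gadd45g, a stress and growth-arrest gene, was 33.6 CPM (27.7 to 40.4) and 124 CPM (115 to 134), a log2 ratio of 1.74. Pclaf, a PCNA-binding protein, had a ratio of 1.54, followed by S100a10 (1.47), Dtl (1.26), Rrm2 (1.23), Ube2c (1.23), Gmnn (1.04), Top2a (1.03) and Ndrg1 (7.96 and 20.9 CPM). Hist1h2ap had the largest, 2.11, but shares 93.4% of its sequence words with other genes, so its value is uncertain. At the other end, Adm, which encodes the vasodilator peptide adrenomedullin, was 105 and 40.1 CPM (-1.28). Then came Pcp4 (-1.18), Pnlip (-1.10), Tmem179 (-1.02), Gpld1 (-1.02), Atp6ap1l (-0.98), Npy (-0.98), Trnp1 (-0.94) and Apoe (-0.90); AY036118 (-1.13) shares 100% of its words and is uncertain. The class markers Pdgfra, Gpr17 and Mbp had ratios of -0.16, -0.08 and 0.21; at the same mix of clusters Pdgfra was 0.024 and Gpr17 0.089, and Mbp was 1.28 with each library clustered alone. Many of the largest and smallest ratios lay nearer 0 at the same mix, among them Pclaf (0.73), Rrm2 (0.60), Ube2c (0.30), Adm (-0.65), Pcp4 (-0.48), Trnp1 (-0.34) and Apoe (-0.28). With 20 CPM added S100a10 was 0.80, Ndrg1 0.55 and Gmnn 0.59.

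Committed or newly formed oligodendrocyte-like cells had higher interferon-response and MHC class I genes and lower cholesterol synthesis genes in the ipsilateral library. Of 17 interferon-response genes 15 were above 0 (median 0.84, percentile 100), with Bst2 at 2.20 and 17.6 CPM and Rtp4 at 5.63 and 19.9 CPM; the median was 0.38 with 20 CPM added and 1.66 with 1 CPM. Of 10 MHC class I genes 8 were above 0 (median 0.39), with B2m, the light chain of MHC class I, at 33.5 and 53.8 CPM and H2-D1 at 40.1 and 88.4 CPM; the median was 0.23 with 20 CPM added and 0.59 with each library clustered alone. All 21 cholesterol synthesis genes were below 0, with a median of -0.41 (percentile 0.0); Hmgcs1, an early enzyme of the pathway, was 609 and 348 CPM and Sc5d 123 and 69.3 CPM. The cholesterol median lay between -0.54 and -0.23 under all alternatives.

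Mature oligodendrocyte markers had a median of -1.97 in the committed class, with Mal at 3957 and 678 CPM, but this value followed the handling of doublets and the clustering. It was 0.35 with doublets kept, -0.53 at a lower expected doublet rate, -0.37 at Leiden resolution 2 and 1.38 with each library clustered alone, so no direction is given. Myelin structure genes, which share members with that list, had a median of -0.74 (13 of 16 below 0), and astrocyte markers -0.45 (5 of 6 below 0). No alternatives are given for these 2 lists, and no direction is read from them. The immediate early median of -0.24, with Btg2 at 98.8 and 30.7 CPM, became 0.65 with doublets kept. Genes of the newly formed stage had a median of 0.47, with Bcas1 at 1670 and 2884 CPM and Tcf7l2 at 489 and 733 CPM, and was 0.10 (percentile 91.4) at the lower expected doublet rate and -0.093 with each library clustered alone. Cluster 1 held 70.5% of contralateral and 54.5% of ipsilateral cells of the class, and cluster 13 the rest.

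Among the largest ratios in the committed class were Ptcra at 6.36 and 37.1 CPM (1.89), Col11a1 at 9.05 and 45.2 CPM (1.84) and Prom1 at 14.9 and 54.9 CPM (1.59). Fbln5 (1.36), Rgs16 (1.35), Gap43 (1.34), Socs3 (1.34), Gadd45g (1.30) and Tmem2 (1.28) followed, with Hist1h2ap (1.34) uncertain as above. With doublets kept Fbln5 was -0.007, Gap43 0.66, Col11a1 1.09 and Tmem2 2.19, with no filter on cells Socs3 was 0.53, and with 20 CPM added Ptcra was 1.11. The smallest were Mal (-2.54), Pdlim2 (-2.43), Ermn (-2.36), Mobp (-2.30), Selenop (-2.27), Clmn (-2.27), Ttll7 (-2.26), Ptprd (-2.25), Prr5l (-2.24) and Efnb3 (-2.23). Mal, Ermn and Mobp are markers of mature oligodendrocytes, and all 10 were above 0 with each library clustered alone. The class markers Pdgfra, Gpr17 and Mbp had ratios of -1.71, 0.10 and 0.06, and no direction is given for them. Pdgfra was 0.043 with doublets kept and 0.009 with each library clustered alone, Gpr17 -0.18 with doublets kept, and Mbp -0.15 with each library clustered alone.

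Mature oligodendrocyte-like cells of the ipsilateral library had higher disease-associated oligodendrocyte genes and MHC class I genes, while myelin genes were near 0. Of 14 measured disease-associated genes 13 were above 0, with a median of 0.57 (percentile 100). C4b, a complement component, was 3.52 CPM (2.63 to 4.61) contralaterally and 61.9 CPM (59.0 to 64.9) ipsilaterally, and the protease inhibitor Serpina3n 0.81 CPM (0.42 to 1.42) and 39.7 CPM (37.4 to 42.1). Socs3, a feedback inhibitor of cytokine signalling, was 21.7 and 121 CPM, and Apoe 96.2 and 409 CPM. The list's median was 0.23 without cluster 18, whose leading genes include C4b and Serpina3n and which held 9 contralateral and 187 ipsilateral cells, 0.17 at the same mix of clusters and 0.19 under the stricter filter, and 0.96 over members with at least 100 UMIs. The same mix used only clusters with at least 10 cells in each library, so for mature cells it also leaves out cluster 18. The medians of 0.23 and 0.17 are thus not separate checks of that cluster. Under the stricter filter mature cells were 26.7% of contralateral and 32.8% of ipsilateral kept cells, against 27.5% and 39.6% in the main setting. Whether the ipsilateral cells lost were those of cluster 18 was not checked, so 0.19 is not read as a separate check either. A cluster drawn mostly from 1 library can reflect that library.

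Of 9 MHC class I genes 8 were above 0 in mature cells (median 0.49, percentile 100). H2-D1, a heavy chain, was 29.9 and 157 CPM, B2m 28.0 and 98.2 CPM and H2-K1 9.40 and 33.1 CPM. The median was 0.31 in cells with no microglia UMI, 0.26 when clustered without response genes and 0.20 with 20 CPM added. Interferon-response genes had a median of 0.13, with 14 of 20 above 0; it was 0.032 (percentile 68.0) in cells with no microglia UMI, 0.048 with 20 CPM added and 0.30 over members with at least 100 UMIs. Ifi27l2a was 5.75 and 74.3 CPM and Ifi27 76.4 and 196 CPM, whereas Ifit3 was 7.24 and 0.77 CPM, 86.0% of its contralateral UMIs coming from a single cell. Reactive glia genes had a median of 0.22 (0.069, percentile 90.2, under the stricter filter), and activated microglia genes, of which Apoe is one, 0.13 (0.046, percentile 92.9, when clustered without response genes). Immediate early genes had a median of 0.32, or 0.14 at the same mix of clusters, with Junb at 466 and 902 CPM, whereas Hspa1a was 59.6 and 28.1 CPM.

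The 16 myelin structure genes had a median of -0.01, 8 above and 8 below 0, with Mobp at 4726 and 3934 CPM and Mag at 4240 and 5004 CPM. Cholesterol synthesis genes had a median of -0.09 (percentile 0.48), with Msmo1 at 508 and 419 CPM; it was 0.026 without cluster 18. Mbp was 5833 and 6544 CPM (0.17), and Pdgfra and Gpr17 had ratios of 0.25 and 0.18 at no more than 22.7 CPM, or -2.27 and -2.79 with each library clustered alone. Markers of other stages and cell types moved as well. OPC stage genes had a median of 0.18 (14 of 15 above 0, percentile 100), OPC markers 0.15 (9 of 10) and committed markers 0.14 (8 of 10); these were -1.86, -2.16 and -1.38 with each library clustered alone and -1.48, -1.55 and -0.88 when clustered without response genes, so no direction is given. Endothelial markers had a median of -0.20 (5 of 6 below 0), neuron markers -0.15 (4 of 5) and neuroblast markers -0.077 (8 of 11). With 20 CPM added these were -0.071, -0.041 and -0.028, with 1 CPM -0.42, -0.32 and -0.17, and the endothelial median was -0.058 (percentile 10.7) with each cell weighted equally. The neuron and neuroblast medians were -0.41 and -0.34 with each library clustered alone and -0.45 and -0.30 when clustered without response genes.

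The share of mature cells with a UMI, each thinned to 18348 UMIs, was 5.96% contralaterally and 20.2% ipsilaterally for C4b, 1.06% and 14.7% for Serpina3n, and 1.06% and 10.9% for Ifi27l2a. Without thinning these were 8.41% and 25.4%, 1.72% and 18.1%, and 1.72% and 12.9%, at median depths of 27269 and 28365.5 UMIs. Neuroblast-like cells at the same thinned depth (medians 16547.5 and 17614 before thinning) gave 0.0% and 3.68% for C4b, 0.0% and 0.61% for Serpina3n, and 0.56% and 1.84% for Ifi27l2a. For H2-D1 the mature shares of 21.3% and 52.5% stood beside 34.1% and 48.5% in neuroblast-like cells, and for Socs3 17.2% and 43.3% beside 30.2% and 44.8%. For Klk6, a protease of mature cells, the mature shares were 19.8% and 26.4% (23.1% and 31.4% without thinning), beside 0.0% and 2.45% in neuroblast-like cells. For the cytokine gene Il33 they were 16.2% and 14.2% (19.3% and 17.9%), beside 1.12% and 0.0%, while its level was 17.4 and 33.4 CPM, so no order is read from its shares. Of 179 contralateral and 163 ipsilateral neuroblast-like cells, 0 with a UMI allows shares of up to 2.04% and 2.24% (upper ends of the exact binomial intervals). Thinning left out 53 contralateral and 106 ipsilateral mature cells, and 227 and 186 neuroblast-like cells, so this background rests on the deeper cells of that class.

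The largest ratios in mature cells were C4b (2.97), Serpina3n (2.94), Ifi27l2a (2.88), Socs3 (2.24), H2-D1 (2.21), Apoe (2.03), Cebpd (1.81), B2m (1.65), H2-K1 (1.40) and Ifi27 (1.30). At the same mix of clusters, which leaves out cluster 18, C4b was 0.66, Serpina3n 1.15, Ifi27l2a 1.82, H2-D1 1.42, Apoe 0.79 and H2-K1 0.84. Under the stricter filter they were 0.90, 1.42, 1.68, 1.32, 0.97 and 0.69, and with 20 CPM added Cebpd was 1.12. C4b shares 48.3% of its sequence words with other genes, H2-D1 26.7%, H2-K1 22.8% and Serpina3n 21.6%, so their levels may be split with near-identical copies. In mm10, C4b lies on chromosome 17 at 34728380 to 34743882, H2-D1 on chromosome 17 at 35262730 to 35267499, and Serpina3n on chromosome 12 at 104406729 to 104414329. The smallest were AY036118 (-0.98), Hspa1a (-0.97), Cacng7 (-0.90), Nutf2 (-0.84), Wdr89 (-0.77), Nme2 (-0.75), Samd1 (-0.74), Kcna2 (-0.64), Hspa1b (-0.64) and Usp50 (-0.60). AY036118, Hspa1a, Hspa1b, Nme2 and Nutf2 share 43.4% or more of their words and are uncertain. By the same measure the level of C4b, at 48.3%, is uncertain too.

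**Figure D2:**
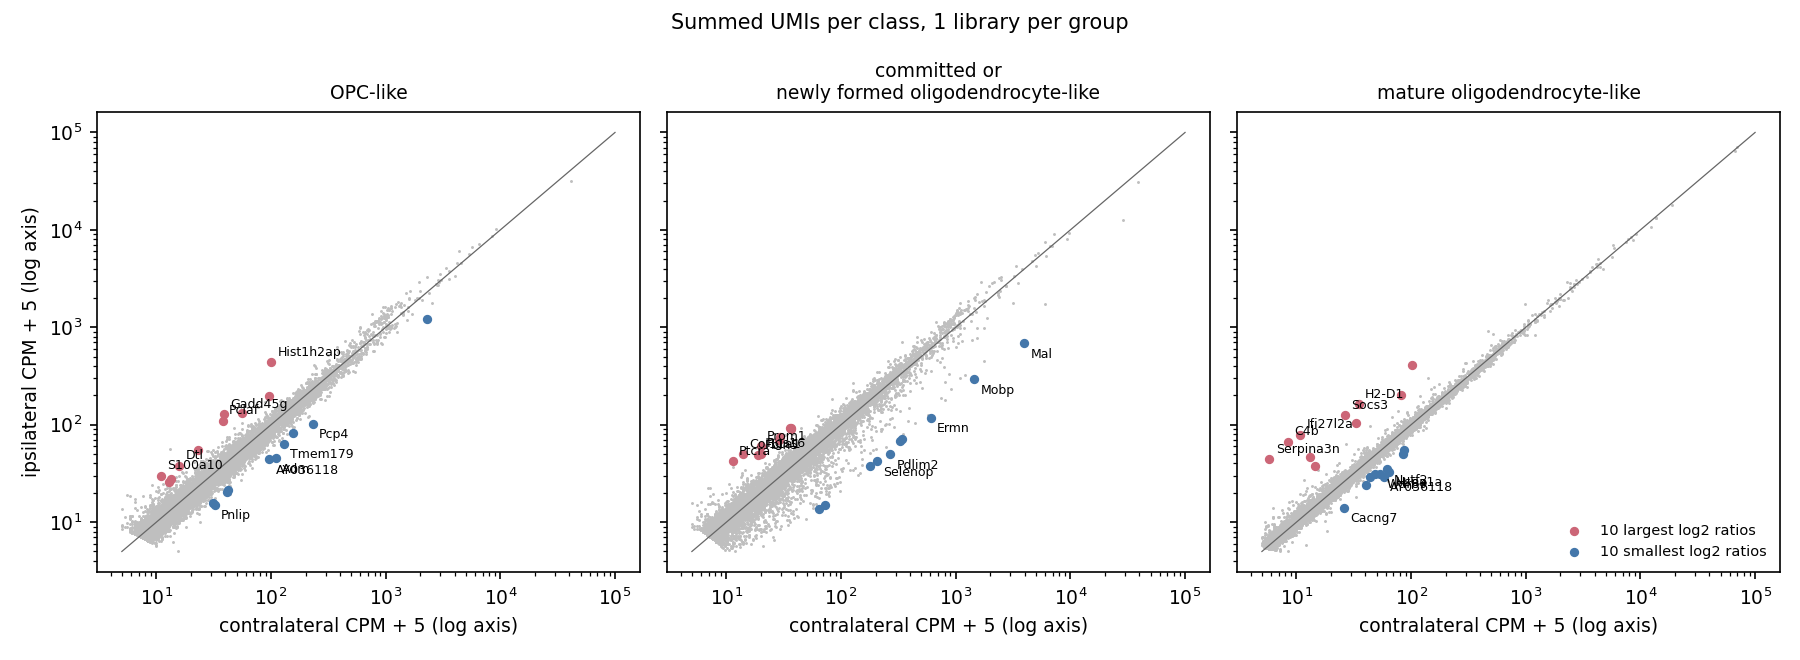
Ipsilateral against contralateral level of each gene (CPM plus 5, log axes) in the 3 oligodendrocyte-lineage classes, 1 library per group; grey points are genes, coloured points the 10 largest and 10 smallest log2 ratios, and the line marks equal levels. In mature cells C4b and Serpina3n lie farthest above the line, at log2 ratios of 2.97 and 2.94.

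**Figure D3:**
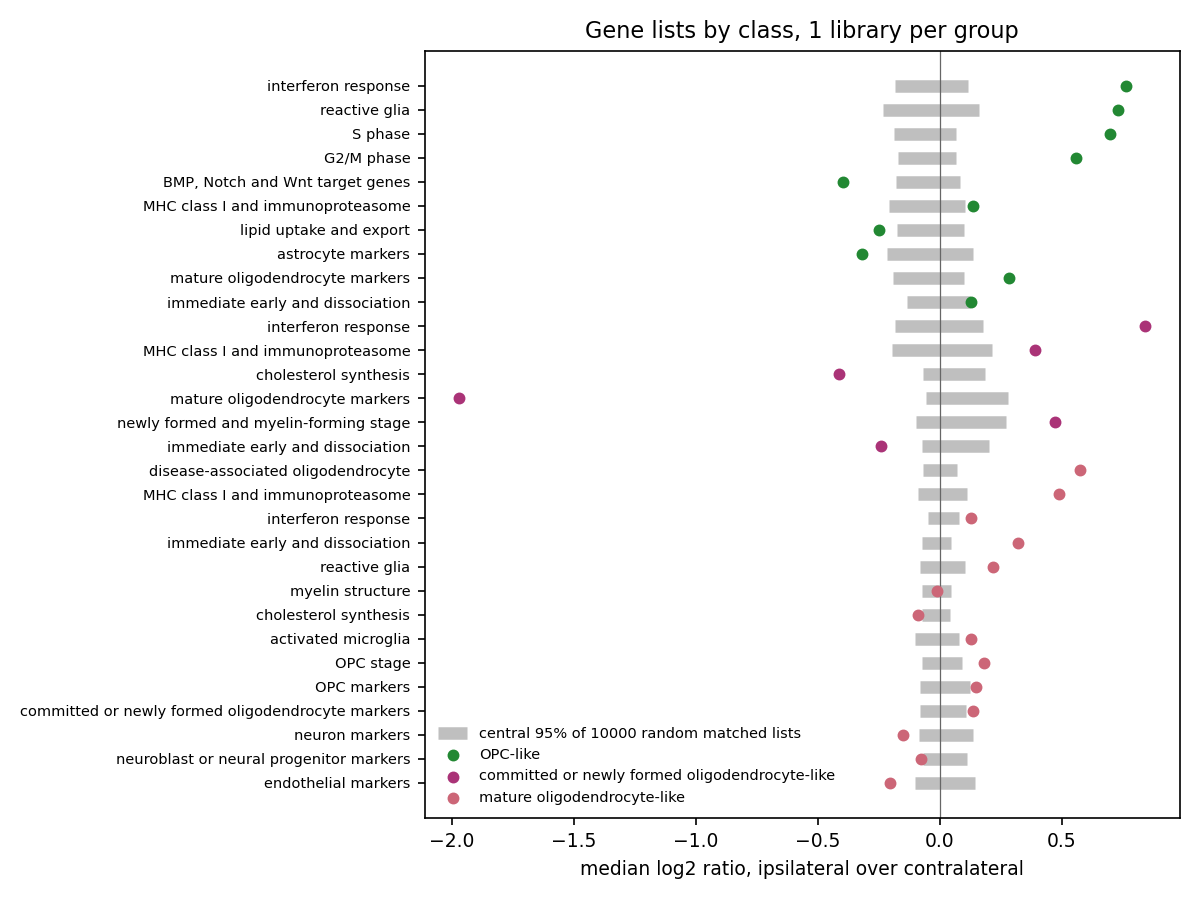
Median log2 ratio (ipsilateral over contralateral) of each described gene list by class; points are medians and grey bars the central 95% of 10000 random lists matched on expression. The disease-associated list in mature cells stands at 0.57 and the cholesterol list in committed cells at -0.41.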

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

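All tests of this part were chosen after the results were seen, except the test of the mature cells lowest for immediate early genes and the tests of shared sequence and exon overlap. No result met the rules for samples apart from their group, since each group is 1 library; the patterns below were picked for their size. The injury itself stays open as an explanation of each pattern and was not tested, because side and library are the same split.

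The higher response genes of ipsilateral mature cells could come from handling, from microglial RNA or from a shift of the whole library. Handling as the whole cause is argued against: in 513 mature cells per library matched on immediate early genes (median -0.018, against 0.32 over all) the disease-associated median was 0.94 (0.77 to 1.11 by counting error) and the MHC class I median 0.37 (0.29 to 0.58). The cells lowest for immediate early genes, at 1.33, decide nothing because their immediate early median was still 0.26. These medians are over members with at least 20 UMIs in the cells used, which may be fewer than over all mature cells. A shift of the whole library by the same log2 amount in each class is argued against on shared members. The bound set was a ratio of medians, class over mature cells, of 0.75. For MHC class I the medians in the other 5 classes were typically 0.37 of that in mature cells (0.20 to 0.51, 6 to 8 members). Over all measured members they were 0.39 in committed and 0.30 in endothelial-like cells against 0.49. For the disease-associated list committed (0.16, 0.08 to 0.22) and endothelial-like cells (0.19, 0.04 to 0.36) argue against it. The typical ratio of that list was 0.52 (0.22 to 0.74), but neuroblast-like cells gave 1.58. OPC-like cells gave 1.11 over 9 shared members, though their median over all 11 was -0.095 (percentile 20.2, 5 above and 6 below 0, 3364 and 2519 CPM in sum). A smaller or partial shift stays open. So does an equal addition of CPM to each class, which was not tested. Microglial RNA as the whole cause is argued against for B2m and H2-D1, whose sum was 197 CPM higher: from their ratio to microglia markers in 7 barcodes with at least 10 marker UMIs, the difference in those markers (18.5 and 22.5 CPM, log2 ratio 0.29, 0.08 to 0.50) would bring 0.13% of it, and at most 1.07% were all ipsilateral marker UMIs microglial. With that largest level taken from each member's ipsilateral CPM, the disease-associated median was 0.565 against 0.574, but the MHC class I median 0.30 against 0.49. Nothing was taken from the contralateral CPM, so 0.30 is a low estimate. A microglial part stays open for the other MHC class I members. The log2 ratio of the microglia markers themselves, 0.29, lay between the bounds set for and against microglial RNA, so by itself it decides nothing. Cells with no microglia UMI gave 0.31 for MHC class I and 0.95 for the disease-associated list over 12 measured members. The 0.95 cannot be set against 0.574, which is over 14 members. In all mature cells the 12 members with at least 100 UMIs gave 0.96.

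The higher cycle genes of ipsilateral OPC-like cells could come from a different mix of their 2 clusters or from free RNA of cycling progenitors. At the same mix the S phase median was 0.36, so the mix does not account for all of it. The G2/M median was -0.25 at the same mix, but the clusters differ in these genes within each library (3.40 and 3.20), so a different mix and a larger share of cycling cells cannot be told apart. Progenitor markers had a median of 0.14 in OPC-like cells (0.09 to 0.35 by counting error), below the S phase value of 0.70. This argues against free progenitor RNA as the whole cause of the S phase values, though the upper end only just met the bound set. For the G2/M list, with a median of 0.56, the comparison was not made, and free progenitor RNA stays open. A larger share of proliferating precursors remains a hypothesis for both lists.

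AY036118, Gm10076, Hist1h2ap, Rpl10-ps3 and Rps27rt were each shifted in a single direction by at least 0.5 in all 6 classes compared. Their median share of sequence words found in other genes was 93.4% against 0.51% for random matched sets (percentile 100), consistent with reads divided differently between near-identical copies. Overlap with exons of other genes stood at 40.0%, the 52.6th percentile, so the set was not unusual for overlap. With only 5 genes this does not exclude overlap, and AY036118 and Hist1h2ap do overlap exons of other genes. No biological explanation was tested.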

How the results depend on the processing

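Neither expected doublet rate was fixed in advance: the lower one was that of a first look, and the default became the main setting after it. Chosen after the results were seen were the single doublet threshold, clustering without response genes, leaving out cluster 18 and the same mix of clusters. Over all alternatives, 436 of 578 list-median values, 783 of 1334 of named genes and 84 of 93 of shares stayed within counting error. Counted as turned in direction were 19, 42 and 1 values. This count leaves out sign changes of results whose main value lay within counting error of no difference. The difference in cycle-gene shares of OPC-like cells, for example, was 4.96 points and became -1.55 points when clustered without response genes. Scaling by trimmed means or median ratios gave no counted turn. The interferon medians of all 3 classes, the S phase and the BMP, Notch and Wnt medians of OPC-like cells, the cholesterol median of committed cells, and the disease-associated and MHC class I medians of mature cells kept their direction under all alternatives run, but the mature interferon median was inside the range of random lists (percentile 68.0) in cells with no microglia UMI. Each group is 1 library, so depth limits only counting error, and no setting measures the spread between animals. No paired analysis was possible because each group holds 1 library and no test was made.

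With no filter on cells, committed cells gave share differences of 0.46 points over kept cells, and a median of -1.75 for the mature marker list. Under the stricter filter, committed cells gave share differences of 3.49 points over the lineage, and medians of 0.025 for the immediate early list and -1.31 for the mature marker list, and ratios of opposite sign for Gpr17 -0.056. Under the stricter filter, mature cells gave share differences of 6.05 points over kept cells and 1.41 points over the lineage, and medians of 0.022 for the cholesterol list, 0.22 for the interferon list and 0.19 for the disease-associated list. With each library clustered alone, OPC-like cells gave medians of 0.56 for the S phase list and 0.39 for the G2/M phase list, and ratios of opposite sign for Gpr17 0.23. With each library clustered alone, committed cells gave share differences of 5.79 points over kept cells and 7.18 points over the lineage, and medians of 0.59 for the MHC class I list, -0.093 for the newly formed stage list, 0.90 for the immediate early list and 1.38 for the mature marker list, and ratios of opposite sign for Mal 2.80, Pdlim2 1.69, Ermn 2.32, Mobp 1.47, Selenop 1.66, Clmn 0.52, Ttll7 1.28, Ptprd 1.64, Prr5l 1.16, Efnb3 0.93, Pdgfra 0.009 and Mbp -0.15. With each library clustered alone, mature cells gave share differences of 8.57 points over kept cells and -2.04 points over the lineage, and medians of 0.23 for the MHC class I list, -1.86 for OPC stage genes, -2.16 for OPC markers and -1.38 for committed markers, and ratios of opposite sign for Pdgfra -2.27 and Gpr17 -2.79. With each cell weighted equally, committed cells gave medians of -0.34 for the cholesterol list, 0.021 for the immediate early list and -1.48 for the mature marker list, and ratios of opposite sign for Gpr17 -0.019 and Mbp -0.007. With each cell weighted equally, mature cells gave a median of 0.74 for the disease-associated list. With cells thinned, OPC-like cells gave medians of 0.35 for the G2/M phase list and 0.28 for the reactive glia list. With cells thinned, committed cells gave a median of 1.07 for the interferon list, and ratios of opposite sign for Mbp -0.049. With cells thinned, mature cells gave medians of 0.24 for the interferon list and 0.82 for the disease-associated list. With 1 CPM added, OPC-like cells gave medians of 1.39 for the interferon list and 0.98 for the reactive glia list. With 1 CPM added, committed cells gave a median of 1.66 for the interferon list. With 1 CPM added, mature cells gave medians of 0.28 for the interferon list, 0.68 for the MHC class I list and 0.99 for the disease-associated list. With 20 CPM added, OPC-like cells gave medians of 0.27 for the interferon list, -0.27 for the BMP, Notch and Wnt list, 0.50 for the S phase list, 0.44 for the G2/M phase list and 0.27 for the reactive glia list. With 20 CPM added, committed cells gave medians of -0.36 for the cholesterol list, 0.38 for the interferon list, 0.23 for the MHC class I list and -1.82 for the mature marker list. With 20 CPM added, mature cells gave medians of 0.048 for the interferon list, 0.20 for the MHC class I list and 0.40 for the disease-associated list. With no minimum of UMIs, OPC-like cells gave a median of 0.14 for the reactive glia list. With no minimum of UMIs, mature cells gave a median of 0.25 for the MHC class I list. In cells with no microglia UMI, OPC-like cells gave a median of 0.24 for the G2/M phase list. In cells with no microglia UMI, committed cells gave medians of 1.02 for the interferon list and -2.12 for the mature marker list, and ratios of opposite sign for Mbp -0.021. In cells with no microglia UMI, mature cells gave medians of 0.032 for the interferon list, 0.31 for the MHC class I list and 0.95 for the disease-associated list. At the same mix of clusters, OPC-like cells gave medians of 0.92 for the interferon list, -0.15 for the BMP, Notch and Wnt list, 0.36 for the S phase list and -0.25 for the G2/M phase list, and ratios of opposite sign for Pdgfra 0.024 and Gpr17 0.089. At the same mix of clusters, committed cells gave medians of -0.31 for the cholesterol list and -1.68 for the mature marker list, and ratios of opposite sign for Gpr17 -0.18. At the same mix of clusters, which here leaves out cluster 18, mature cells gave medians of 0.018 for the cholesterol list and 0.17 for the disease-associated list. With doublets kept, committed cells gave medians of 0.65 for the immediate early list and 0.35 for the mature marker list, and ratios of opposite sign for Fbln5 -0.007, Mal 0.62, Pdlim2 0.29, Ermn 0.35, Mobp 0.78, Selenop 0.55, Ttll7 0.053, Ptprd 0.66, Prr5l 0.41, Efnb3 0.38, Pdgfra 0.043 and Gpr17 -0.18. At the lower expected doublet rate, committed cells gave medians of 0.22 for the immediate early list and -0.53 for the mature marker list, and ratios of opposite sign for Selenop 0.021 and Gpr17 -0.18. With 1 doublet threshold for both libraries, committed cells gave a median of -1.42 for the mature marker list. At Leiden resolution 2, committed cells gave medians of -0.23 for the cholesterol list, 0.57 for the immediate early list and -0.37 for the mature marker list, and ratios of opposite sign for Ptprd 0.27 and Gpr17 -0.21. Clustered without response genes, committed cells gave medians of -0.31 for the cholesterol list and -0.32 for the mature marker list, and ratios of opposite sign for Gpr17 -0.21. Clustered without response genes, mature cells gave medians of 0.26 for the MHC class I list, -1.48 for OPC stage genes, -1.55 for OPC markers and -0.88 for committed markers, and ratios of opposite sign for Pdgfra -1.48 and Gpr17 -2.16. At Leiden resolution 0.5, mature cells gave medians of 0.25 for the interferon list and 0.94 for the disease-associated list. With at least 100 summed UMIs, mature cells gave medians of 0.30 for the interferon list and 0.96 for the disease-associated list. Without cluster 18, mature cells gave medians of 0.026 for the cholesterol list, 0.29 for the interferon list and 0.23 for the disease-associated list. For these values the cause was not tested.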

Other observations

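The tests of C4b or Serpina3n cells below were chosen after the results were seen. Astrocyte-like, endothelial-like and neuroblast-like cells were compared as secondary classes, with no alternatives run.

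Astrocyte-like cells of the ipsilateral library had higher Gfap, the astrocyte filament gene that marks reactive astrocytes, at 186 CPM (163 to 211) and 435 CPM (397 to 475). Their interferon-response median was 0.86, with 11 of 13 genes above 0, and their G2/M median -1.08, with Top2a at 35.4 and 10.5 CPM. Transcripts of the oligodendrocyte lineage were higher beside these, with medians of 0.59 for OPC markers (8 of 9 above 0), 0.56 for OPC stage genes (13 of 14), 0.38 for myelin structure genes (14 of 16) and 0.34 for mature oligodendrocyte markers (11 of 12). Adamts18 (1.40), Pllp (1.28) and Apod (1.26, a mature oligodendrocyte marker) were also among the largest ratios, as was Dlx1 (1.74), with 63.5% of its UMIs in a single cell. At the other end Gdf15 (-3.47), Gadd45a (-3.08) and Cdkn1a (-1.57) drew 86.0%, 80.7% and 52.5% of their contralateral UMIs from single cells, and Nme2 (-1.26) shares 47.9% of its sequence words with other genes.

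Endothelial-like cells had interferon-response and MHC class I medians of 0.39 and 0.30, with 19 of 20 and 12 of 12 genes above 0. Oligodendrocyte-lineage lists lay higher in these cells, with medians of 1.11 for OPC stage genes (7 of 7 above 0), 0.82 for committed markers (7 of 10), 0.70 for mature markers (12 of 12) and 0.54 for myelin structure genes (16 of 16), and 16 of 28 lists were above the range of random lists. Astrocyte markers went the other way, with a median of -0.75 (5 of 5 below 0). Ctgf was 289 and 99.0 CPM, and Itga4, an integrin subunit, 124 and 50.8 CPM; Cenpa (-1.35), Plekhh2 (-1.18) and Acad9 (-1.14) were also among the smallest ratios. The largest ratios rested mostly on single cells: Ackr1 had 106 ipsilateral UMIs, all in 1 cell, and the largest cell held 86.1% for Lcn2, 95.6% for Bmp4, 82.7% for Gpr17 and 63.0% for Bcas1. In neuroblast-like cells the mature marker and myelin structure medians were 0.38 (13 of 13 above 0) and 0.37 (15 of 16), and 16 of 36 lists were above the range of random lists. Endothelial markers had a median of -0.57 in these cells (6 of 6 below 0). Thrsp was 30.5 and 69.0 CPM, Zic1 9.38 and 24.6 CPM, and Ifi27 29.8 and 59.1 CPM, while Nrcam was 32.1 and 16.4 CPM. Scgb1a1 (1.70) had 96.3% of its UMIs in 1 cell, and Hist1h2ap, Hist1h2af, Hist1h2ab, Nutf2 and Nme2 are uncertain for shared sequence.

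A hypothesis is that C4b or Serpina3n and Ifi27l2a mark 1 state of ipsilateral mature cells. At 18348 UMIs per cell, C4b or Serpina3n was found in 34.8% of 92 cells with an Ifi27l2a UMI and 24.8% of 754 cells without. The difference of 9.98 points had an interval of -0.18 to 21.1, so the data do not decide it.

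A second hypothesis is that cells with C4b or Serpina3n have lower cholesterol synthesis genes. Between 304 ipsilateral mature cells with and 648 without these UMIs, the cholesterol median was -0.29 (percentile 0.0), with 19 of 21 genes below 0, at median depths of 27531.5 and 28674 UMIs. This may reflect a difference of state, but the cells come from 1 library and were split on genes seen to differ, so it remains a hypothesis.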
